A study of Homo sapiens with 7 samples.

How the data were processed

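Total RNA of HK-2 cells was sequenced by a commercial 3' digital mRNA-seq service from 125 ng of input, single-end with 100 cycles, per the labels' protocols. The deposited table holds raw counts per Ensembl gene for 7 libraries, in whole numbers and with totals between 5654957 and 8455963. STAR, HTSeq and edgeR and the genome build hg38 are named in the submitters' processing notes without version or role. The annotation release, the strand setting and any use of molecular identifiers are not given in the sources used here. Reads without molecular identifiers are not independent molecules, and reads of overlapping, antisense or near-identical genes cannot be told apart with an unknown strand setting. A 3' method counts transcript ends, so no splice form was measured.

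The table had 33694 rows, of which 16136 held a count of 0 in every library and 0 were totals or unassigned classes. Symbols were taken by Ensembl ID, because 615 rows had no deposited symbol and 28 symbols had been turned into dates. Of the IDs, 32807 matched the name table and 33132 were found in GENCODE release 29, from which positions on GRCh38 were taken. All 7 value columns matched a sample by name, and 0 were left out.

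Groups came from the sample titles. The comparison was siGLUT2 against scrambled over all 7 libraries with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total 15), TMM scaling, robust estimateDisp and glmQLFit, glmQLFTest without covariates, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values are scaled by TMM. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry (limma 3.58.1). Library measures were compared by exact two-sided permutation tests of the difference of means over the 35 splits, whose smallest p is 0.0286. A floor of 3 counts stands for a count of 0. Principal components used log2 CPM with a prior count of 2. The p-values measure the spread between these libraries, which the labels call biological replicates of 1 cell line.

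The lists, tests and rule for naming genes were set before the data were examined. The rule names SLC2A2, the 12 largest rises and the 12 largest falls with an adjusted p below 0.05, a mean of at least 5 CPM and no overlap between groups, up to 4 members per list with the smallest adjusted p (or, where fewer than 2 pass, up to 2 with the highest CPM), and the 5 genes with the highest CPM. Some genes that the rule takes are not reported here by name, while counts and list tests include them. The 36 lists cover hexose transporters, glycolysis and lactate, gluconeogenesis, the pentose phosphate pathway, MondoA and ChREBP targets, TCA cycle, nuclear oxidative phosphorylation, mitochondrially encoded genes, fatty acid oxidation, cholesterol biosynthesis, fatty acid synthesis, unfolded protein response, ATF4 response, interferon-stimulated genes, antigen presentation, p53 targets, S phase, G2 and mitosis, proximal tubule, tubular injury, extracellular matrix, hypoxia, NRF2, NF-kB, lysosome and autophagy, hexosamine, polyol and fructose, glycogen, insulin and mTOR, RNA interference, ribosomal proteins, heat shock, other nephron segments, fibroblasts and pericytes, endothelium and leukocytes.

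Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other low-count filters, thinning to the smallest total, a replicate block, each library left out in turn, an adjusted p of 0.01, non-robust estimation, glmTreat against 1.2-fold and protein-coding genes alone. Where the filter removed SLC2A2, its value came from the fit without the filter. Chosen after seeing the data were counts divided by the spread index of each group, a GC offset per library (GC content known for 99.8% of tested genes), leaving out genes whose 3' UTR holds GACCTTA or ACCTTAA, and limma-voom with a quality weight per group. The spread index of a group is the median over genes of the chi-square of counts against library totals per degree of freedom, divided by the median that sampling alone gives, and the correction used its value at mean counts of 10 to 50.

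For the 3' UTR scan, the longest annotated 3' UTR of at least 50 bases was taken for each of 10101 genes with a mean of at least 5 CPM. Log2 fold change was regressed on the presence of each 7-base word with UTR length, UTR GC content and expression (each with its square), and each word's statistic was scaled by the median and the median absolute deviation over all 16384 words into a robust z. It ran in Python 3.11.15 with numpy 2.4.6.

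Scripts were tested on simulated data. For the comparison of siGLUT2 with scrambled, counts of 12404 genes were drawn with 200 genes changed, and edgeR, which kept 12167 of them, recovered 21 of 67 genes changed 1.5-fold, 46 of 67 changed 2-fold and 59 of 66 changed 4-fold, with 4 false calls among 130. In a run with no gene changed, all genes were given their group's spread index at mean counts of 10 to 50. Of 12138 genes 0 were called and 6.69% had an unadjusted p below 0.05. The measured index rose to 8.5 in scrambled and 25.7 in siGLUT2 libraries above 1000 counts. This run therefore understates the spread of genes counted more often. Camera called 1 raised list of 30 and 0 of the others over 12148 genes. Genes were drawn independently there, so the preset correlation was not tested. In the data the estimated correlation reached 0.471, for the mitochondrially encoded genes. In the 3' UTR scan over 10101 genes, each of 3 planted words with a log2 shift of -0.3 came out at rank 1.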

Results

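The transcriptome of HK-2 cells, an immortalised line of human kidney proximal tubule epithelium, was measured 96 h after transfection with 50 nM siRNA directed at GLUT2, the facilitative glucose transporter encoded by SLC2A2, or with a scrambled siRNA. There were 4 scrambled libraries (replicates 1 to 4) and 3 siGLUT2 libraries (replicates 2 to 4), which the labels call biological replicates. Total counts were 7148654, 8455963, 7850308 and 5654957 in the scrambled libraries and 5881366, 6914302 and 6435237 in the siGLUT2 libraries. The single comparison of the design asks which transcripts differ between cells that received the GLUT2 siRNA and cells that received the scrambled siRNA. Unless stated otherwise, an adjusted p is that of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, fold changes are log2 siGLUT2 over scrambled ± SE, and CPM values are mean ± SD with n = 4 scrambled and n = 3 siGLUT2 libraries.

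SLC2A2 (ENSG00000163581, GRCh38 chromosome 3, 170996348 to 171026750, minus strand, protein coding) was counted 13, 13, 7 and 17 times in the scrambled libraries and 0 times in each siGLUT2 library. The pooled scrambled level was 1.72 CPM (exact Poisson 95% interval 1.27 to 2.26). If reads were independent, the siGLUT2 total of 0 would allow up to 0.156 CPM (3 counts over the group). The transcript would then be at least 8.17-fold lower at the lower end of the scrambled interval (11-fold at the pooled level). The adjusted p was 0.0085, and the exact two-sided permutation test of CPM gave p = 0.0571 over the 35 splits of the libraries, whose smallest possible p is 0.0286. Without scrambled replicate 4 the adjusted p was 0.0538, and with a correction for spread chosen after seeing the data it was 0.0842 in the SLC2A2 knockdown check. Of 593 other genes with 40 to 60 counts over the scrambled libraries, 21 (3.54%) were also at 0 in all 3 siGLUT2 libraries. These intervals and floors cover only the counting error of independent reads. At mean counts of 10 to 50 the spread index was 4.29 in scrambled and 8.68 in siGLUT2 libraries. The 8.17-fold value is therefore not a firm lower bound.

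**Figure D1:**
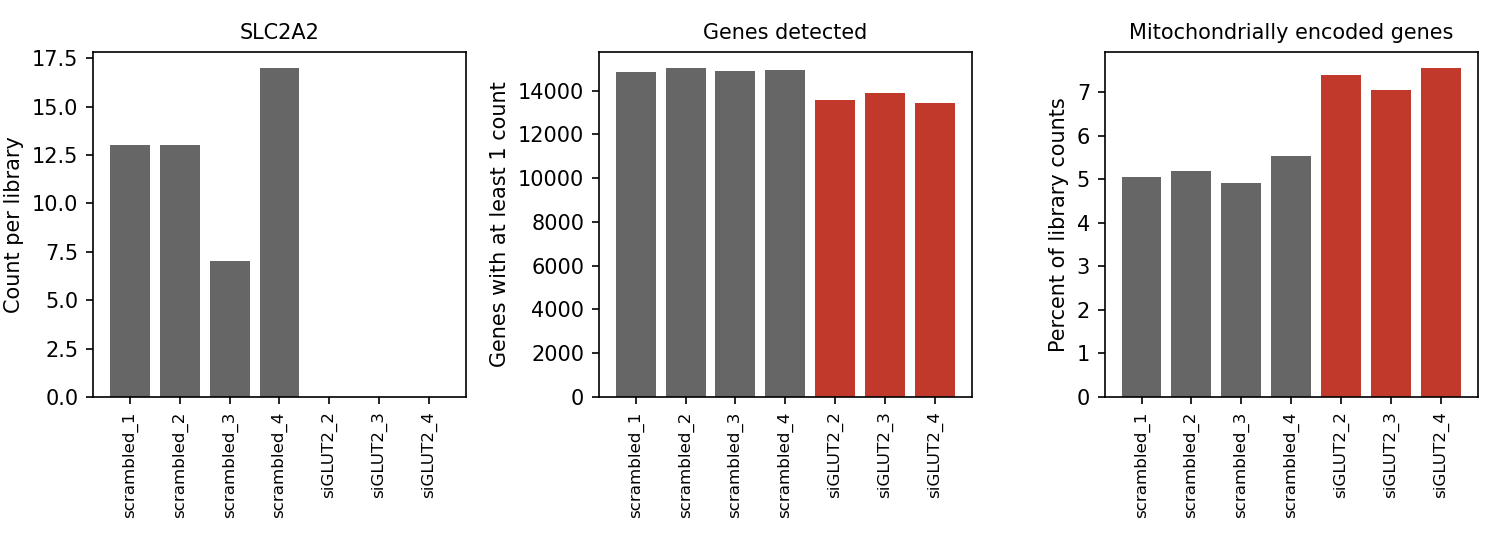
Bars give, for each of the 7 libraries, the SLC2A2 count (left), the number of genes with at least 1 count (middle) and the percent of counts on mitochondrially encoded genes (right), with scrambled libraries in grey and siGLUT2 libraries in red. SLC2A2 was at 0 in the 3 siGLUT2 libraries, which also had fewer genes detected and a larger mitochondrial share than each scrambled library.

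The siGLUT2 libraries held fewer detected genes and more mitochondrial counts. Genes with at least 1 count numbered 14924 ± 82.2 (SD, n = 4) in scrambled and 13632 ± 235 (SD, n = 3) in siGLUT2 libraries (exact permutation p = 0.0286, adjusted over 5 measures 0.0476). Mitochondrially encoded genes took 5.17% ± 0.264 and 7.33% ± 0.265 of counts, and the 50 most counted genes took 16.7% ± 0.294 and 18.1% ± 0.376, with the same exact permutation p of 0.0286 for both measures (adjusted 0.0476). Total counts (exact permutation p = 0.257, adjusted 0.321) and the share of ribosomal protein genes, 10.8% ± 0.277 and 10.8% ± 0.0975 (exact permutation p = 0.857, adjusted 0.857), did not pass. The first principal component held 44.1% of the variance and separated the groups, while the second and the third component (20.5% and 14.7%) spread the siGLUT2 libraries from each other.

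After siGLUT2, 3509 of 12404 tested genes changed, 1723 higher and 1786 lower, and 1030 of them changed at least 2-fold (487 higher, 543 lower). CPM values of the groups did not overlap for 3235 of the changed genes. Over all tested genes 35.1% had no overlap, where chance gives 5.71%. The median log2 fold change of all tested genes was -0.0029.

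The largest rises among genes with a mean of at least 5 CPM and no overlap were in ODAPH, which rose from 0.665 ± 0.867 to 12.8 ± 0.411 CPM (adjusted p = 4.1e-05), and PLPP4, a lipid phosphate phosphatase, from 0.765 ± 0.526 to 11.6 ± 3.8 CPM. LUM, the matrix proteoglycan lumican, rose from 1.86 ± 0.877 to 23.9 ± 4.67 CPM. SEMA7A, a membrane-anchored semaphorin, rose from 13.6 ± 2.51 to 141 ± 26.5 CPM (3.37 ± 0.16, adjusted p = 2.68e-12), and SHISA2 rose by a log2 fold change of 3.20 ± 0.18. SIGLEC15, a sialic acid-binding lectin, rose by 3.18 ± 0.20 and TMEM158 by 3.07 ± 0.34. G0S2, an inhibitor of the lipase ATGL, rose from 30.9 ± 3.7 to 237 ± 34.3 CPM (adjusted p = 5.47e-13). ANGPTL4, an inhibitor of lipoprotein lipase, rose by 2.91 ± 0.47, the receptor tyrosine kinase MERTK by 2.83 ± 0.42, the vitamin D receptor VDR by 2.82 ± 0.35 and the phosphatase DUSP10 by 2.75 ± 0.27.

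The largest falls were in ZBED2, from 16.6 ± 1.37 to 0.218 ± 0.189 CPM (-6.19 ± 0.53, adjusted p = 1.35e-08), and CMC1, a protein linked to cytochrome c oxidase assembly, from 16.2 ± 4.89 to 0.432 ± 0.749 CPM. TAF9B fell from 25.9 ± 2.94 to 1.58 ± 1.14 CPM (-4.00 ± 0.38), and MRPL2, a mitochondrial ribosomal protein, from 18.4 ± 9.83 to 1.18 ± 1.23 CPM. TNFAIP6 changed by -3.55 ± 0.66, MAL by -3.51 ± 0.52 and the matrix protein EFEMP1 by -3.46 ± 0.54. MAPK8IP2 changed by -3.44 ± 0.52, MAP7D2 by -3.41 ± 0.51, PCMTD2 by -3.34 ± 0.53 and CYP24A1, the vitamin D 24-hydroxylase, by -3.33 ± 0.46. The 7-base words GACCTTA or ACCTTAA stood in the annotated 3' UTR of 6 of the 12 largest falls (CMC1, TAF9B, EFEMP1, MAPK8IP2, MAP7D2 and CYP24A1) and of 2 of the 12 rises (SHISA2 and DUSP10). Either word stood in 1672 of all 10101 genes scanned. The words were picked by a scan of these same fold changes, described below, so their share among the largest falls is no separate support.

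**Figure D2:**
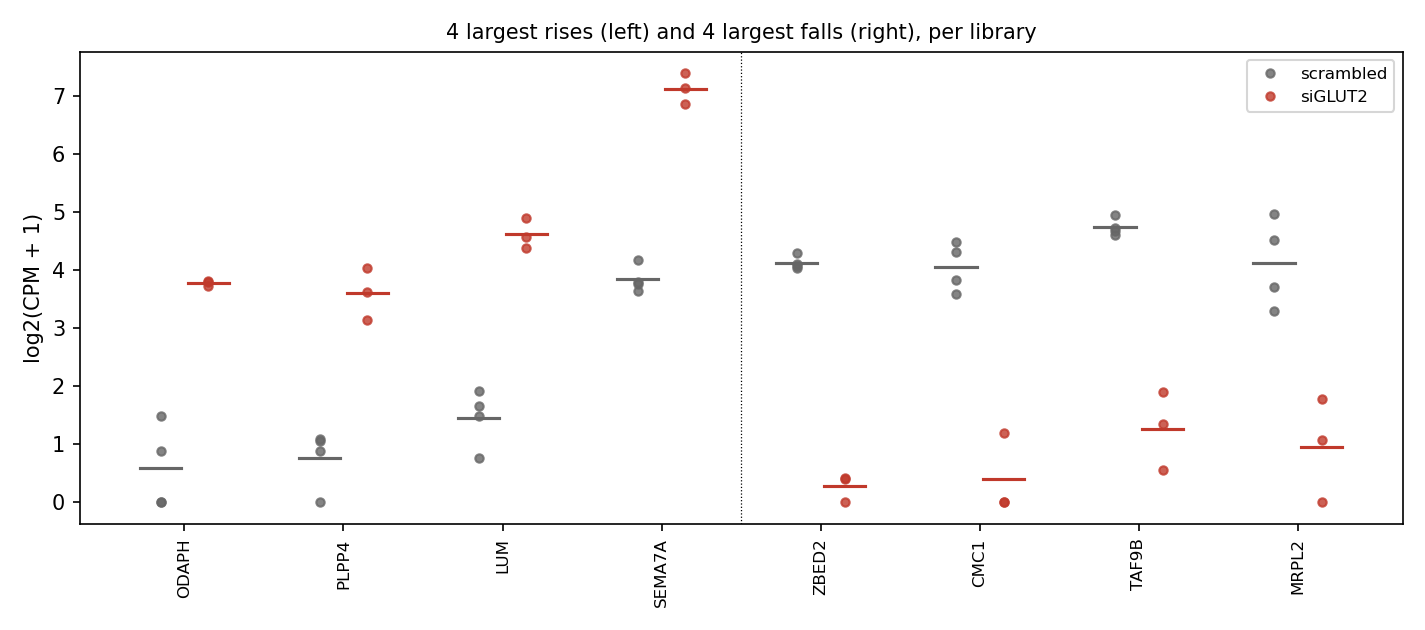
Points give log2(CPM + 1) of each library, with scrambled libraries in grey and siGLUT2 libraries in red, and short lines give group means, for the 4 largest rises (left of the dotted line) and the 4 largest falls (right). The groups did not overlap for any of these genes, and ZBED2 and CMC1 were among the falls that reached 0 CPM in a siGLUT2 library.

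Of 36 gene lists fixed before the data were examined, 33 had at least 5 tested members, and camera with a preset correlation of 0.01 called 12 of them, 8 higher and 4 lower. With an estimated correlation 2 lists were called, the cell cycle lists. In the lists below where 0 members passed in a direction by edgeR, DESeq2 and limma-voom also gave 0, and an unadjusted p below 0.05 gave at most 1. Besides genes for which it is stated, GACCTTA or ACCTTAA stood in the 3' UTR of HMGCS1, ELOVL6, ELOVL5, MTHFD2, TAP2, ABCC4, P4HA1, ABCC3, GFPT1, TNRC6A and PODXL. These genes include rises as well as falls.

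Cell cycle genes fell. Of 44 tested members of the G2 and mitosis list, 33 fell and 1 rose (34 and 1 adjusted over the list alone), with a median of -0.63 (camera adjusted p = 8.83e-14, adjusted p = 0.0054 with an estimated correlation). BUB3, a spindle checkpoint protein, went from 214 ± 12 to 62.9 ± 11.6 CPM, ASPM changed by -0.96 ± 0.10, the topoisomerase TOP2A by -0.73 ± 0.08 and NUSAP1 by -0.98 ± 0.11. The 3' UTRs of BUB3 and NUSAP1 held GACCTTA or ACCTTAA. Of 40 S phase genes, 28 fell and 0 rose (29 and 0 adjusted over the list alone), with a median of -0.69 (camera adjusted p = 2.35e-12, adjusted p = 0.0054 with an estimated correlation). The replicative helicase subunit MCM5 changed by -1.27 ± 0.11 and MCM4, of the same complex, went from 400.0 ± 32.7 to 199.6 ± 22.7 CPM. The ribonucleotide reductase subunit RRM1 changed by -0.85 ± 0.08 and the licensing factor CDT1 by -1.07 ± 0.11.

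In the glycolysis and lactate list 12 of 22 tested genes fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 6.55e-05, adjusted p = 0.126 with an estimated correlation). SLC16A1, the lactate transporter MCT1, went from 330 ± 40.3 to 58.3 ± 1.17 CPM (-2.50 ± 0.11), and its 3' UTR held ACCTTAA. Lactate dehydrogenase LDHA changed by -0.83 ± 0.08, ENO1 by -0.80 ± 0.11 and TPI1 by -0.83 ± 0.12, and LDHA and ENO1 have pseudogenes that can share reads. Among 12 hexose transporters 1 rose and 3 fell, SLC2A2 included (1 and 3 adjusted over the list alone, camera adjusted p = 0.407). SLC50A1, a sugar transporter, fell (-2.11 ± 0.36). SLC2A3 (GLUT3), whose reads can be shared with SLC2A14 (0 counts in each group), rose (0.90 ± 0.19). SLC2A1 (GLUT1) fell from 242 ± 10.2 to 197 ± 11.9 CPM, with an adjusted p of 0.0161 that became 0.053 without scrambled replicate 3. In the pentose phosphate list 3 of 10 fell and 0 rose (3 and 1 adjusted over the list alone, camera adjusted p = 0.258), among them RPIA (-1.17 ± 0.21) and PRPS2 (-0.52 ± 0.14). Of 17 glycogen genes 2 rose and 5 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.258), among them the phosphorylases PYGL (-1.22 ± 0.18) and PYGB (-0.71 ± 0.15), PGM1 (-0.60 ± 0.14) and the synthase GYS1 (-0.70 ± 0.17).

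Other sugar-linked lists were not called, except the hexosamine list. Of its 12 tested genes 5 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0369, adjusted p = 0.388 with an estimated correlation), with PGM3 at 0.86 ± 0.11, GNPDA1 at 0.79 ± 0.10, UAP1 at 0.73 ± 0.19 and GFPT1, the rate-limiting enzyme of the pathway, at 0.39 ± 0.10. That call was lost without scrambled replicate 2 (0.0676) or 3 (0.0554) or siGLUT2 replicate 3 (0.092), with the stricter low-count filter (0.0539) and with 3 corrections chosen later, for spread (0.0587), GC content (0.0534) and the words above (0.0567). Among 7 glucose-responsive MondoA and ChREBP targets 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.417). ARRDC3 fell (-0.79 ± 0.18), KLF10 rose (0.73 ± 0.19), and TXNIP was at 156 ± 25.7 and 201 ± 25.1 CPM (0.36 ± 0.12, adjusted p = 0.028, and 0.104, 0.054 or 0.107 without scrambled replicate 3, scrambled replicate 4 or siGLUT2 replicate 2). Of 5 gluconeogenic genes tested 0 passed by edgeR (0 adjusted over the list alone, 1 at an unadjusted p below 0.05, camera adjusted p = 0.622). G6PC3 was at 56.6 ± 8.62 and 43.8 ± 14.2 CPM (adjusted p = 0.16, and 0.0182 without siGLUT2 replicate 4) and PPARGC1A at 27.8 ± 3.38 and 28.0 ± 6.36 CPM. In the polyol and fructose list 1 of 6 rose, AKR1A1 (0.79 ± 0.13), and 1 fell, the aldose reductase AKR1B1 (-0.65 ± 0.09), the same adjusted over the list alone (camera adjusted p = 0.753).

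Among 66 nuclear oxidative phosphorylation genes 6 rose and 17 fell (6 and 18 adjusted over the list alone, camera adjusted p = 0.0369, adjusted p = 0.415 with an estimated correlation), with COX6A1 at -1.71 ± 0.14, COX8A at -0.92 ± 0.11, NDUFB8 at -0.81 ± 0.10 and NDUFS3 at -0.99 ± 0.13. The call was lost without scrambled replicate 1 (0.0774) or 3 (0.0621) or siGLUT2 replicate 4 (0.0532), with the stricter filter (0.0507) and without the genes holding the words above (0.0608), of which COX6A1 was a member. Of the 13 mitochondrially encoded genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 6.55e-05, adjusted p = 0.378 with an estimated correlation). MT-ND3 rose from 6049 ± 227 to 14833 ± 477 CPM, MT-ATP6 from 4948 ± 107 to 8865 ± 832, MT-ND2 from 6468 ± 394 to 10416 ± 37.9, MT-CO3 from 8700 ± 495 to 10799 ± 1363 and MT-CYB from 2568 ± 96.3 to 3371 ± 280, while MT-ND4 was at 6208 ± 456 and 6017 ± 367 CPM (adjusted p = 0.686). Apart from MT-CYB, these 5 genes had the highest mean CPM of all, and reads of mitochondrial genes can be shared with nuclear copies.

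Of 31 genes in the TCA cycle list 2 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.738), with IDH3B at -0.68 ± 0.12, IDH1 at -0.52 ± 0.13, DLAT at 0.66 ± 0.17 and DLD at -0.57 ± 0.16, whose adjusted p of 0.0096 became 0.0623 without siGLUT2 replicate 3. Among 27 fatty acid oxidation genes 3 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.738), with ECHS1 at -1.01 ± 0.14, ACADM at -0.78 ± 0.16, ACSL4 at 0.72 ± 0.11 and HADHB at 0.81 ± 0.14.

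Cholesterol biosynthesis genes rose. Of 25 tested, 13 rose and 3 fell (14 and 4 adjusted over the list alone, camera adjusted p = 0.000325, adjusted p = 0.114 with an estimated correlation). INSIG1, an SREBP regulator, went from 217 ± 13.2 to 534 ± 0.791 CPM (1.30 ± 0.08), and HMGCS1 rose by 0.61 ± 0.09. Of 19 fatty acid synthesis genes 4 rose and 5 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.954), with ELOVL6 at 1.30 ± 0.15, ACLY at 0.44 ± 0.08, AGPAT2 at -1.05 ± 0.18 and ELOVL5 at -0.66 ± 0.13.

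Inflammatory and antigen presentation genes rose. In the NF-kB list 15 of 31 rose and 3 fell (17 and 3 adjusted over the list alone, camera adjusted p = 0.000370, adjusted p = 0.0675 with an estimated correlation), with the inhibitor NFKBIA at 0.68 ± 0.08, PTGES at 1.14 ± 0.15, the cytokine IL11 at 1.22 ± 0.19 and the adhesion molecule ICAM1 at 0.79 ± 0.13. In the antigen presentation list 8 of 16 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.106 with an estimated correlation), with HLA-B at 0.68 ± 0.09, B2M at 0.60 ± 0.08, ERAP1 at 1.10 ± 0.17 and TAP2 at 0.63 ± 0.13. Reads of HLA genes can be split between near-identical paralogs, so the HLA-B value is uncertain. Of 32 interferon-stimulated genes 1 rose and 7 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.417). IFI44L rose (2.42 ± 0.14), and BST2 (-0.96 ± 0.12) and HERC5 (-0.86 ± 0.18) fell.

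Lysosomal, antioxidant and endoplasmic reticulum genes rose as lists. In the lysosome and autophagy list 21 of 55 rose and 4 fell (23 and 4 adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.106 with an estimated correlation), with IDS at 1.08 ± 0.13, CTSA at 0.80 ± 0.10 and the autophagy receptor SQSTM1 at 0.61 ± 0.09. The proton pump subunit ATP6V1B2, whose 3' UTR held both words, fell from 82.0 ± 3.57 to 16.8 ± 1.78 CPM. In the NRF2 list 10 of 33 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.117 with an estimated correlation), with ABCC3 at 1.35 ± 0.21, TXNRD1 at 0.67 ± 0.10 and FTH1 at 0.48 ± 0.08. That call was lost without the genes holding the words (0.111). In the unfolded protein response list 9 of 20 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.0257, adjusted p = 0.351 with an estimated correlation), with the chaperone HSPA5 at 0.49 ± 0.09, HERPUD1 at 0.87 ± 0.15, HYOU1 at 0.63 ± 0.11 and CANX, whose 3' UTR held GACCTTA, at -0.71 ± 0.08. The call was lost with the stricter filter (0.0539) and with the spread correction chosen later (0.0587). FTH1 has processed pseudogenes that can share reads.

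Further stress lists were not called. Of 30 ATF4 integrated stress response genes 7 rose and 4 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.258), with MTHFD2 at 0.74 ± 0.11, STC2 at 0.86 ± 0.15, GARS1 at 0.49 ± 0.11 and PHGDH at -0.76 ± 0.15. Of 27 p53 targets 8 rose and 4 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.283), with GADD45A at 0.87 ± 0.13, CCNG1 at 0.67 ± 0.14, PLK2 at -0.63 ± 0.09 and XPC at -0.78 ± 0.18. Of 29 hypoxia targets 6 rose and 8 fell (7 and 8 adjusted over the list alone, camera adjusted p = 0.753), with P4HA1 at -0.71 ± 0.10 and NDRG1 at -0.93 ± 0.14. Its median was 0.0092 and its mean 0.05, while the test pointed down. Of 16 heat shock genes 4 rose and 5 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.954), with HSPB1 at -1.01 ± 0.10, HSF1 at -0.71 ± 0.15, BAG3 at 0.96 ± 0.19 and HSPA1A, which shares reads with HSPA1B, at 0.87 ± 0.14. The median was 0.0011 and the mean 0.16, and the test pointed down.

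Of 50 proximal tubule genes only 19 had enough counts to be tested, so the list test leaves out most of the list. Of these 19, 4 rose and 3 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.799), with the efflux pumps ABCB1 at -1.69 ± 0.14 and ABCC4 at -0.65 ± 0.14 and the peptidases ENPEP at 1.82 ± 0.39 and MME at 0.75 ± 0.20. The median was 0.04 and the mean -0.013, and the test pointed down. Of 29 tubular injury and repair genes 10 rose and 9 fell (11 and 9 adjusted over the list alone, camera adjusted p = 0.877). PLAUR (1.70 ± 0.12) and CD44 (1.11 ± 0.10) rose, and the keratins KRT7 (-2.17 ± 0.16) and KRT18 (-0.76 ± 0.08) fell. Its median was -0.08 and its mean 0.0067, and the test pointed up. In the extracellular matrix and mesenchymal transition list 20 of 49 rose and 12 fell (21 and 14 adjusted over the list alone, camera adjusted p = 0.0879, adjusted p = 0.414 with an estimated correlation). Fibronectin FN1 went from 370 ± 32.8 to 1093 ± 50.8 CPM (1.56 ± 0.08), COL6A1 rose by 0.93 ± 0.09, and COL8A1 changed by -1.49 ± 0.12. This list was called without scrambled replicate 4 (0.0453), without siGLUT2 replicate 2 (0.0278), with no low-count filter (0.0316) and with the corrections chosen later for spread (0.0282), GC content (0.0235) and the words above (0.0253).

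Among markers of other cell types, 2 of 5 tested fibroblast and pericyte genes rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.106, adjusted p = 0.356 with an estimated correlation, and 0.0483 without siGLUT2 replicate 2), LUM and COL1A1. COL1A1 was at 9.4 ± 1.45 and 16.6 ± 2.33 CPM (0.82 ± 0.27, adjusted p = 0.026, and 0.052 to 0.0775 without scrambled replicate 1, 3 or 4 or siGLUT2 replicate 4). The endothelial list had 2 tested members and no list test. EGFL7 was at 30.5 ± 4.2 and 18.6 ± 1.21 CPM (adjusted p = 0.0094, and 0.196 with the GC correction chosen later), and ERG at 1.45 ± 0.592 and 1.09 ± 0.947 CPM. The list of other nephron segments also had 2 tested members, PODXL at 9.04 ± 3.65 and 8.85 ± 3.59 CPM and AQP3 at 0.889 ± 0.638 and 1.63 ± 1.42 CPM. Of 16 leukocyte markers 0 had enough counts to be tested.

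Of 34 insulin and mTOR signalling genes 7 rose and 7 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.988). The insulin receptor gene INSR went from 23.1 ± 1.28 to 7.05 ± 2.45 CPM (-1.71 ± 0.27) and IRS2 changed by -1.33 ± 0.12, while IRS1 rose by 0.95 ± 0.16 and PRKAB2 by 1.38 ± 0.23. The 3' UTRs of INSR, IRS2 and IRS1 held GACCTTA or ACCTTAA. The median was 0.11 and the mean -0.04, and the test pointed down. Of 13 RNA interference genes 4 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.258), with TNRC6A at 0.93 ± 0.12, AGO2 at 0.61 ± 0.12, TNRC6B at 0.46 ± 0.11 and AGO4 at 0.76 ± 0.27, whose adjusted p of 0.0353 lay between 0.0528 and 0.108 without any 1 of the libraries except siGLUT2 replicate 4, and was 0.0504 with the group quality weights chosen later. Of 69 cytosolic ribosomal protein genes 14 rose and 14 fell (18 and 16 adjusted over the list alone, camera adjusted p = 0.954), with RPL19 at -0.67 ± 0.08, RPL3 at -0.68 ± 0.08, RPS3 at -0.46 ± 0.08 and RPS12 at 0.59 ± 0.09. The median was 0.05, the mean -0.02, camera pointed up and fry down. Ribosomal protein genes have many processed pseudogenes, and these values are uncertain to that extent.

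**Figure D3:**
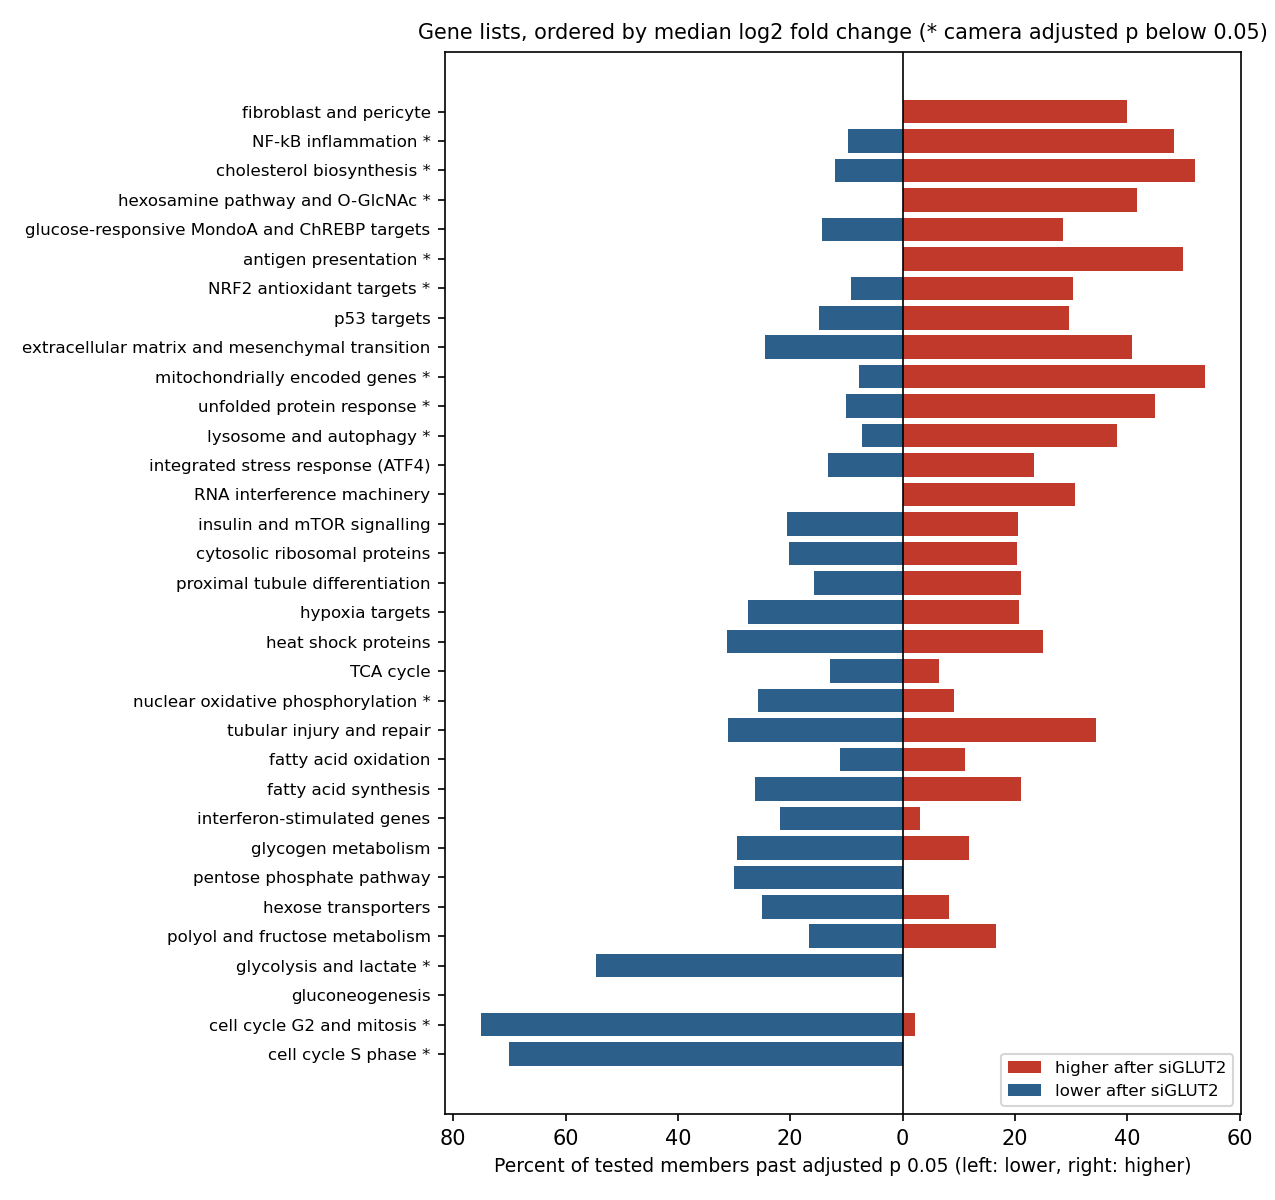
Bars give, for the 33 tested lists, the percent of tested members that were higher (red, right) or lower (blue, left) after siGLUT2 at an adjusted p below 0.05, ordered by the list's median log2 fold change, with an asterisk where camera called the list. Of the cell cycle lists 33 of 44 and 28 of 40 members were lower, and of the cholesterol list 13 of 25 were higher.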

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

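The tests on composition, depth, repeat reads and culture differences below were chosen after the results they bear on were seen, as was the leaving out of genes holding the words.

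Among 157 values tested in the scrambled group, 5 had a library far from the others, where chance gives about 1 in 20. G0S2 stood at 36.4 CPM in scrambled replicate 1 against 28.6 to 29.7 in the others (gap over range 0.854). PLK2 was at 460 CPM in replicate 3 against 416 to 422 (0.858). COL6A1 was at 196 CPM in replicate 4 against 207 in the others (0.933). NFKBIA was at 241 CPM in replicate 1 against 263 to 267 (0.843). TNRC6B was at 109 CPM in replicate 4 against 86.6 to 90.4 (0.832).

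Of 35 splits, 1, the real one, gave as many genes changed (3509), higher, lower or changed at least 2-fold. The highest other split gave 0. Each other split mixes the groups, so the real difference widens its spread within groups and lowers its count. The share of 1 in 35 is also the smallest that these splits can give, so they do not exclude chance. For the number of called lists, 12, the splits do not exclude chance, since 3 of 35 splits gave as many and the highest other gave 12. The other splits with 12 set all 3 siGLUT2 libraries and 1 scrambled library against the remaining scrambled libraries, and so hold much of the real contrast. Splits with 1 siGLUT2 library in the group of 3 gave 0 to 2 lists. The count concerns the number of lists, not any single list.

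Some falls after siGLUT2 went with a sequence in the 3' UTR. The word GACCTTA had the lowest robust z of all 16384 words, -11.23, followed by ACCTTAA at -10.34. These overlap as the sites of a single guide seed. Seed-matched repression by the GLUT2 siRNA is a candidate explanation for part of the falls. Of the 802 genes holding GACCTTA, 28.6% were lower and 10.8% higher, and of the 1244 holding ACCTTAA, 22.1% and 11.6%. Of the 1672 genes holding either word, 395 (23.6%) were lower and 11.8% higher, against 15.1% and 17.0% of the 8429 holding neither word. Most of the lower genes scanned held neither word. UTR base composition is argued against, because the lowest of 629 other words of the same bases reached -6.63. That word, GCCTTAA, shares CCTTAA with ACCTTAA. For the rises, a strong release from a single seed of the scrambled siRNA is argued against by a highest z of 4. A weaker release was not tested, since the planted words had a log2 shift of -0.3. The siRNA sequence was not used here, so the guide's identity stays open, as do consequences of GLUT2 loss for the genes that hold neither word, of which 1271 were lower. Those genes may still hold related words, since CCTTAAA (-6.94), GCCTTAA (-6.63), ACCTTAT (-5.41), TACCTTA (-5.28) and AACCTTA (-5.14) were also among the lowest. Their coding sequence and shorter 3' UTRs were not searched.

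GACCTTA lies in SLC2A2 itself, at GRCh38 chromosome 3, 170998087 to 170998093 on the minus strand, within CGGACTTCTGTGGACCTTATG, in coding sequence of exon 11 of 1 transcript and in the annotated 3' UTR of 2 others (exon 10). SLC2A2 transcripts hold 17.3% of all 7-base words, so this match alone says little. The z of GACCTTA was -8.04 on odd chromosomes (rank 2) and -8.83 on even chromosomes (rank 1), and its reverse complement had -0.17.

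The fall of the cell cycle lists is not accounted for by GACCTTA or ACCTTAA in the searched 3' UTRs of their own members. Only 2 tested S phase genes and 3 tested G2 and mitosis genes held a word, and without word-holding genes both lists stayed past the threshold, the larger adjusted p being 3.41e-13. An indirect effect of another repressed gene, or of GLUT2 loss, was not tested, nor were related words or sites in coding sequence.

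Fewer genes were detected and the spread was wider in siGLUT2 libraries. Shallower sequencing is argued against, because at equal totals they still had 1188 fewer genes (14788 ± 99.5 against 13601 ± 218). Fewer distinct molecules, each read more often, may contribute: the spread index at counts of 10 to 50 was 2.02 times higher (8.68 against 4.29) and rose only 1.43-fold up to counts of 300 to 1000. Cultures that differ more from each other may contribute too, since the excess of the index above 1000 counts was 4.11 times larger per count. Both stay open. SLC2A2 had only 50 counts over the scrambled libraries, and the effect of either on it was not tested.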

How the results depend on the processing

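The corrections for spread, GC content and group quality and the leaving out of word-holding genes were chosen after seeing the data. Counts of changed genes stayed within 1.5 times of 3509 under each alternative except an adjusted p of 0.01 (2264 genes changed, 1097 genes higher, 1167 genes lower) and glmTreat (2305), both stricter by construction. Leaving out a library gave 2796 to 3778 changed genes, and leaving out word-holding genes 2858. The share of higher calls lay between 46.7% and 57.4%, the latter with the GC offset. Scaling moved the median of all genes by less than 0.1.

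In the SLC2A2 knockdown check the adjusted p was 0.00104 (DESeq2) to 0.092. It missed the threshold in the replicate block (0.092), without scrambled replicate 4 (0.0538) and with counts divided by the spread index (0.0842), and without a library it ranged from 0.0121 to 0.0538. Fewer libraries or counts entered these fits. The libraries of the block stayed below the threshold when fitted without it, so fewer libraries alone do not account for that miss. The stricter filter and the leaving out of word-holding genes removed it. Replicate numbers showed no clear pairing of the libraries (correlations of deviations of 0.01, 0.015 and -0.003). siGLUT2 replicates 2 and 3 correlated best with their own number, and siGLUT2 replicate 4 did not. Correlations this small do not tell whether a number marks a shared batch. The replicate block called 2635 genes and 11 lists, against 2834 and 11 in the same libraries without it. Not called with the block were nuclear oxidative phosphorylation (0.0724), SLC2A1 (0.0517), EGFL7 (0.0598), AGO4 (0.0601) and COL1A1 (0.102). Of these, nuclear oxidative phosphorylation (0.0774), AGO4 (0.0572) and COL1A1 (0.0775) were also not called in the same libraries without the block.

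Fry called 23 lists and camera with an estimated correlation 2, against 12; fry asks whether members move one way, not whether they differ from other genes. The other alternatives called 9 to 14. Of 149 further named genes, 143 were called, 136 of these kept call and direction in each alternative that tested them, and 0 reversed. The rule picks called genes by large changes or small adjusted p, so their stability does not carry over to all calls. Of the 3509 calls, 2765 to 3101 were shared when a library was left out and 2607 with the replicate block. The shared calls kept their direction. Genes near 1 CPM are limited by depth.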

Other observations

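The YAP and TAZ test below was chosen after WWTR1 had been seen.

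The smallest p of all genes belonged to WWTR1, which encodes the transcriptional coactivator TAZ and lies outside the rule for names, so it was chosen after its values were seen. It fell from 620 ± 22.6 (SD, n = 4) to 136 ± 7.6 CPM (SD, n = 3), a log2 fold change of -2.18 ± 0.09 (edgeR adjusted p = 2.07e-13), and its 3' UTR held GACCTTA. Among the other 11 genes with the smallest p, also chosen after their values were seen, the histone chaperone subunit SSRP1 fell (-1.90 ± 0.10), as did the cargo receptor LMAN2 (-2.51 ± 0.14), and both held GACCTTA. S100A2 fell (-1.70 ± 0.10) and AMIGO2 rose from 176 ± 4.21 to 498 ± 31.7 CPM, and neither held a word. VDR rose while CYP24A1, a gene it is known to induce, fell, and the 3' UTR of CYP24A1 held both words.

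A hypothesis was that the fall of WWTR1 lowers YAP and TAZ target genes. Over 21 tested of 22 listed targets, 5 rose and 4 fell, with a median of 0.02, and camera gave p = 0.308 (p = 0.397 with an estimated correlation). Among those that rose were NT5E (2.56 ± 0.19), the largest change, CCN1 (0.79 ± 0.10) and ANKRD1 (1.35 ± 0.17). IGFBP3 (-1.34 ± 0.16) and F3 (-1.13 ± 0.21) were among those that fell, and CCN2 did not pass (-0.12 ± 0.15). As a set the targets were not called lower, and camera pointed up. The outcome set against the hypothesis was a median of 0 or above, which was met narrowly. Because 4 targets fell, the hypothesis is left undecided.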
